A study of Mus musculus with 7 samples.

How the data were processed

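Epithelial endometrial cells of mice without ovaries were profiled by sequencing of total RNA in 7 libraries: 2 with estradiol, 1 with vehicle, 2 with tamoxifen and 2 with tamoxifen plus alpelisib. The authors name CASAVA, Bowtie and Cufflinks, without versions, and the deposited values are FPKM, as read from the values themselves: they are not whole numbers, although the name of the table speaks of counts. The only genome build in the submitters' notes is a human one, while the gene symbols are mouse symbols, so no genomic position is given. How reads were assigned to near-identical gene copies is not given in the sources used here, which limits single members of the Klk1b, Sprr2, globin and H2-Q families. The table holds 24353 genes, of which 6155 are at 0 in every library, and 23432 symbols matched the mouse annotation regardless of case. A total of 27 names turned into dates by a spreadsheet were tested but are not named.

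The design, fixed before the data were examined along with the gene lists and the rule for named genes, assumed counts and a test for counts. As the values are FPKM, limma-trend on log2(FPKM + 1) was used instead, with no scaling beyond FPKM, on the 12314 genes with an FPKM of at least 1 in at least 1 library. The pseudocount of 1 understates changes of genes with low values. A model of the 4 group means over all 7 libraries left 3 residual degrees of freedom, to which the empirical Bayes prior added 3.27, and gave all 6 comparisons between groups. The vehicle group has 1 library, from 1 mouse or a pool (not given in the sources used here), and is assumed to vary like the others; if it is a pool, that assumption and the meaning of each vehicle value change. P values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The mouse numbers 1 and 2 do not pair the groups and were not used as a block.

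The 22 pathway lists and 18 cell type marker lists were written from background knowledge. They were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. Members were also counted by direction past the threshold over all genes, and after adjustment over the list alone. The genes named are, per comparison, the 10 highest and the 10 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean FPKM of at least 5 and every library of one group above every library of the other, leaving out predicted models, pseudogenes and histones, together with up to 4 members of lowest p of each list described and a set of genes fixed in advance, not all of which are given. The comparisons of tamoxifen plus alpelisib with vehicle and with estradiol name fewer of these. Genes that lists share are named where overlap is given.

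Alternatives planned in advance were median-of-ratios size factors computed on FPKM, no filter on low values, a pseudocount of 0.1, robust empirical Bayes, a fold of at least 2, each replicate left out in turn, a replicate block, and only the compared groups in the fit. Quantile normalization and a filter of 1 FPKM in at least 2 libraries were added after the data were seen. The overlap of the tamoxifen response with the changes under alpelisib and with the estradiol response was set against 20 simulated sets with no effect. For alpelisib this covered the share opposed, and for estradiol Pearson's r, the covariance and the count of shared calls. The method was tested on simulated data of 12314 genes with 200 changed. At 4-fold 93.5% to 99% were recovered, at 2-fold 51.5% to 53.5% between groups of 2 and 0% against vehicle, and at 1.5-fold 0%. At most 17 unchanged genes were called and 0 changed genes with the wrong sign. Far more genes passed in the data, which loosens the Benjamini-Hochberg cutoff: 4807 for tamoxifen against vehicle, of which 2746 changed at least 2-fold. The recovered shares therefore do not carry over to the data. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.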

Results

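RNA from endometrial epithelial cells of C57BL/6 female mice without ovaries was sequenced in 7 libraries. The mice were oophorectomized at 6 to 7 weeks of age, and 18 of them were randomized, 6 per arm, to vehicle, to tamoxifen at 0.5 mg per day, or to tamoxifen with alpelisib at 30 mg/kg per day, each for 28 days. Tamoxifen is a selective estrogen receptor modulator that acts as a partial agonist in the uterus, and alpelisib inhibits the alpha isoform of the PI3K catalytic subunit. A further 2 mice received estradiol from a pellet of 0.01 mg. The libraries comprise 2 of estradiol, 1 of vehicle, 2 of tamoxifen and 2 of tamoxifen plus alpelisib, so vehicle values have no replicate and no SD. Whether the vehicle library comes from 1 mouse or a pool is not given in the sources used here. Values are fragments per kilobase of transcript, scaled to the library's total (FPKM), and log2 fold changes are given ± SE from the fit. Depth is not given in the sources used here. The lowest cluster of values of 4144 genes with 1 transcript, taken as a single fragment, puts it near 16.6 M fragments for estradiol 1, 19.5 for vehicle, 18 and 16.6 for tamoxifen 1 and 2, and 17.3 and 16 for tamoxifen plus alpelisib 1 and 2. Estradiol 2 shows no such cluster (26 genes at the lowest step and 53 at the next, against 165 to 207 and 107 to 137 in the other 6 libraries), so its depth is left open. The sum of FPKM over genes was 323309 and 264322 in the estradiol libraries, 383379 in vehicle, 320527 and 403562 with tamoxifen, and 355967 and 378400 with tamoxifen plus alpelisib. Between 10109 and 11167 genes reached an FPKM of 1 per library. Ribosomal RNA precursor (Rn45s) had an FPKM of 764 and 2276 in the estradiol libraries and between 189 and 530.4 in the other 5.

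Each comparison below was made over 12314 genes, and 40 gene lists were tested in each. Median-of-ratios scaling moved the median log2 fold change of all genes by over 0.1 in 5 of the 6 comparisons: from -0.12 to 0.00 for tamoxifen against vehicle, from 0.12 to 0.00 for estradiol against vehicle, from -0.26 to -0.02 for tamoxifen against estradiol, from -0.15 to -0.02 for tamoxifen plus alpelisib against vehicle, and from -0.26 to -0.01 for tamoxifen plus alpelisib against estradiol. Fold changes are to be read against these medians. With the correlation between genes estimated instead of preset at 0.01, 0 of the 99 list calls by camera held, although 4 to 7 lists per comparison had an unadjusted p under 0.05 there. That alternative rests on 3 residual degrees of freedom, and its lowest adjusted p in each comparison lay between 0.247 and 0.328. A call lost there therefore does not tell whether correlation between genes produced it. The rotation test fry, which asks only whether a list moves one way on balance, gave 130 calls.

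Tamoxifen against vehicle addresses what the drug does to this epithelium in the absence of ovarian estrogen. Tissue kallikrein Klk1 rose from an FPKM of 57 to 13337 ± 5627 (SD, n = 2), a log2 fold change of 7.78 ± 0.42 (adjusted p = 0.000108). Its neighbour Klk1b27 rose by 8.41 ± 0.21 (adjusted p = 1.89e-05), although near-identical kallikrein copies can share reads. Lactotransferrin (Ltf), an estrogen-induced secretory protein of the mouse uterus, rose from 83.1 to 2548 ± 12.4 (SD, n = 2; log2 4.92 ± 0.30, adjusted p = 0.000148). Among the other strongest increases were Spink12, Prss29, Apobec2, the diamine oxidase Aoc1 (7.71 ± 0.18), arginase Arg1 (6.99 ± 0.30), the steroid hydroxylase Cyp21a1 (6.83 ± 0.16) and urate oxidase Uox (6.73 ± 0.17), with adjusted p from 1.89e-05 to 7.10e-05. The largest decreases were in the matrix protein Tgfbi, from 519.9 to 5.23 ± 0.179 (SD, n = 2; log2 -6.39 ± 0.16, adjusted p = 1.89e-05), and in Mt3, Il17rb, Pla2g10, Timp3, Krt17, Ctgf, Efhd1, Cldn1 and Igfbp3, with log2 fold changes from -6.30 to -4.82. The tight junction gene Cldn1 had an FPKM of 61.4 in vehicle and 0.669 ± 0.115 with tamoxifen (SD, n = 2).

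The list of uterine estrogen response genes had 30 measured members, of which 19 rose and 4 fell with tamoxifen (21 and 4 when adjusted over the list alone). Taken as 1 list they had camera adjusted p = 4.98e-08, and adjusted p = 0.328 with an estimated correlation. Complement factor Cfb rose by 5.25 ± 0.23, and the peptidyl arginine deiminases Padi2 and Padi4 by 6.21 ± 0.30 and 4.39 ± 0.22. Greb1 rose by 1.51 ± 0.23 (adjusted p = 0.00374), whereas the log2 fold change of the progesterone receptor gene Pgr was -0.01 ± 0.15 (adjusted p = 0.977) and that of Esr1 was -0.46 ± 0.30 (adjusted p = 0.267). Cyclin D1 (Ccnd1) fell, with a log2 fold change of -2.45 ± 0.19 (adjusted p = 0.000324). In the mitosis list 15 of 30 members rose and 0 fell (22 and 0 when adjusted over the list alone), with Ccnb1 at 1.28 ± 0.18 and Ccna2 at 1.01 ± 0.15. By camera the list had adjusted p = 3.51e-07, and adjusted p = 0.328 with an estimated correlation. Mki67, at a log2 fold change of 0.96 ± 0.34, did not pass (adjusted p = 0.067), but passed with a pseudocount of 0.1 (adjusted p = 0.0326; 0.0326 to 0.195 over the alternatives). Interferon response genes rose in 23 of 29 cases and fell in 0 (24 and 0 when adjusted over the list alone), led by Rtp4 (2.88), Ifi44 (2.21) and Oas1a (2.78). The camera test gave adjusted p = 1.43e-11, and adjusted p = 0.328 with an estimated correlation. Over the alternatives at the preset correlation, this list was also called with estradiol and with tamoxifen plus alpelisib against the same vehicle library. It was called in none of them between the treated groups. A low value in the vehicle library would give this pattern too. Innate defense genes rose in 7 of 22 cases and fell in 4 (10 and 4 when adjusted over the list alone), among them Pigr, the receptor that carries polymeric antibodies across epithelia (5.73 ± 0.21). Camera on this list gave adjusted p = 0.00192, and adjusted p = 0.539 with an estimated correlation. The innate list shares C3, Cfb, Lcn2, Ltf and Muc1 with the estrogen list.

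Sterol synthesis genes rose in 9 of 23 cases and fell in 1 (10 and 3 when adjusted over the list alone), including Cyp51 (1.61 ± 0.16) and Mvd (1.86 ± 0.23). For the whole list, camera adjusted p = 0.0047, and adjusted p = 0.539 with an estimated correlation. Of the components of the PI3K, AKT and mTOR pathway, 6 of 36 rose and 7 fell (6 and 6 when adjusted over the list alone). Tested together with camera, these genes had adjusted p = 0.954, and adjusted p = 0.98 with an estimated correlation. That list's median log2 fold change was -0.23 and its mean -0.11, while the direction of its test was upward. Pik3ca had a log2 fold change of -0.12 ± 0.19 (adjusted p = 0.638). The regulatory subunit gene Pik3r3 rose by 1.64 ± 0.20, as did Pdk1 by 1.36 ± 0.19, whose symbol in the mouse denotes a pyruvate dehydrogenase kinase. Targets of FOXO transcription factors, which AKT restrains, rose in 4 of 30 cases and fell in 12 (5 and 12 when adjusted over the list alone). As a set they had camera adjusted p = 0.209, and adjusted p = 0.735 with an estimated correlation. Foxo1 itself fell (-1.03 ± 0.16, adjusted p = 0.00377) and Txnip rose (1.45 ± 0.22, adjusted p = 0.00374). The insulin and IGF axis had 1 member higher and 9 lower of 17 (1 and 9 when adjusted over the list alone; camera adjusted p = 0.0376, and adjusted p = 0.348 with an estimated correlation), and its call was lost without tamoxifen replicate 2 and with a filter of 1 FPKM in at least 2 libraries (adjusted p = 0.070 and 0.193; 0.0257 to 0.193 over the alternatives). Igf1r fell (-1.72 ± 0.22), as did Irs2 (-1.86 ± 0.16), which stood at an FPKM of 3.34 in vehicle, and Igf1, Irs1 and Insr had adjusted p of 0.892, 0.36 and 0.742.

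Most markers of stroma, endothelium and smooth muscle were lower with tamoxifen than in the vehicle library. Whether the vehicle library held more of these cells, which could lower other transcripts named above too, was not tested. Stromal markers fell in 16 of 17 cases and rose in 1 (1 and 16 when adjusted over the list alone), with Dpt at -3.32 ± 0.17 and Vim, at 51.7 FPKM in vehicle and 7.1 ± 1.43 with tamoxifen (SD, n = 2), at -2.71 ± 0.20; 8 of the 18 genes of this list sit in another list too. Their camera adjusted p was 7.86e-05, and adjusted p = 0.328 with an estimated correlation. Endothelial markers fell in 8 of 11 cases and rose in 1 (1 and 10 when adjusted over the list alone; camera adjusted p = 0.00412, and adjusted p = 0.348 with an estimated correlation), and smooth muscle markers fell in 6 of 9 and rose in 0 (0 and 8 when adjusted over the list alone; camera adjusted p = 0.00814, and adjusted p = 0.328 with an estimated correlation). Alongside these, collagen and matrix genes fell in 19 of 31 cases and rose in 3 (3 and 20 when adjusted over the list alone): Thbs1 fell (-3.59 ± 0.19), whereas the matrix metalloproteinase gene Mmp7 rose (5.14 ± 0.34). Taken as 1 list they had camera adjusted p = 0.000795, and adjusted p = 0.328 with an estimated correlation. Wnt signaling genes fell in 14 of 24 cases and rose in 3 (3 and 14 when adjusted over the list alone), with the R-spondin receptor gene Lgr5 at -2.73 ± 0.15 and Wnt7a, a ligand of the luminal epithelium, at -2.60 ± 0.21. By camera the list had adjusted p = 0.00897, and adjusted p = 0.328 with an estimated correlation. Squamous keratinocyte markers rose in 8 of 14 cases and fell in 2 (8 and 2 when adjusted over the list alone), with Krt6a at 3.80 ± 0.16 and Krt5 at 4.06 ± 0.20 against Krt17 at -5.44 ± 0.30. The camera test gave adjusted p = 0.00634, and adjusted p = 0.413 with an estimated correlation. Tamoxifen metabolism and xenobiotic genes fell in 12 of 19 cases and rose in 3 (3 and 13 when adjusted over the list alone), with the retinal dehydrogenase Aldh1a1 at -3.42 ± 0.21 and the sulfotransferase Sult1d1 at -3.46 ± 0.26. Camera on this list gave adjusted p = 0.020, and adjusted p = 0.539 with an estimated correlation. Ribosomal protein genes fell in 11 of 74 cases and rose in 0 (0 and 0 when adjusted over the list alone). For the whole list, camera adjusted p = 8.19e-06, and adjusted p = 0.735 with an estimated correlation. The erythroid markers rose in 5 of 5 cases (5 and 0 when adjusted over the list alone), Hba-a2 from 0.00694 to 315 ± 56.1 (SD, n = 2), although alpha globin copies can share reads. Tested together with camera, these genes had adjusted p = 0.000505, and adjusted p = 0.328 with an estimated correlation.

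In this comparison 4807 genes passed an adjusted p of 0.05, 1838 higher and 2969 lower with tamoxifen, and 2746 of them changed at least 2-fold. With median-of-ratios scaling 5013 genes passed, 2387 of them higher and 2626 lower. Because vehicle has 1 library, its spread was taken to be that of the other groups. Those groups did not vary alike. A chi-square of replicate differences against fragment sampling had medians of 3.73 with tamoxifen and 1.08 with tamoxifen plus alpelisib (0.455 from sampling alone). With estradiol it was 5.02, where the depth of library 2 is left open. The fit pools their spread, and which of them vehicle resembles is not known. Among the 40 lists, camera called 10 upward and 8 downward.

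**Figure D1:**
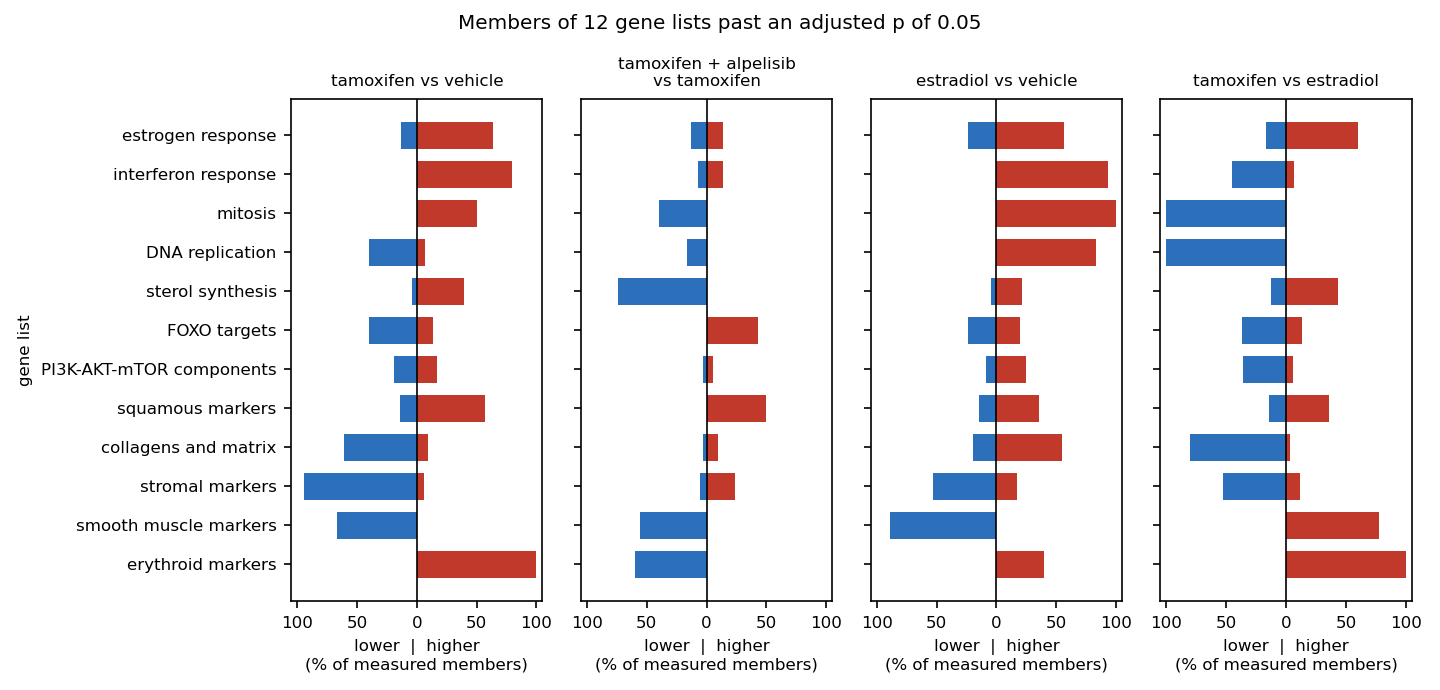
Percent of each list's measured members that were higher (red, to the right) or lower (blue, to the left) at an adjusted p of 0.05, for 12 gene lists (vertical axis) in 4 comparisons. Sterol synthesis genes point upward with tamoxifen (9 of 23 higher) and downward when alpelisib was added (17 of 23 lower), and mitosis genes were higher in 30 of 30 cases with estradiol.

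Tamoxifen plus alpelisib against tamoxifen addresses what inhibition of PI3K alpha changes in the epithelium exposed to tamoxifen. Genes of sterol synthesis fell in 17 of 23 cases and rose in 0 (0 and 18 when adjusted over the list alone). As a set they had camera adjusted p = 2.57e-13, and adjusted p = 0.281 with an estimated correlation. Squalene epoxidase (Sqle) went from 12.3 ± 0.298 to 1.61 ± 0.114 FPKM (SD, n = 2 each; log2 -2.34 ± 0.12, adjusted p = 0.00156), and Idi1 from 19.7 ± 0.341 to 3.23 ± 0.124 (log2 -2.29 ± 0.12, adjusted p = 0.00156). Fdps and Msmo1 followed at -1.72 ± 0.16 and -1.58 ± 0.15. FOXO targets rose in 13 of 30 cases and fell in 0 (18 and 0 when adjusted over the list alone). Their camera adjusted p was 5.09e-08, and adjusted p = 0.281 with an estimated correlation. Foxo1 went from 5.88 ± 0.205 to 14.1 ± 0.242 FPKM (SD, n = 2 each; log2 1.13 ± 0.13, adjusted p = 0.00644), Pdk4 rose by 1.36 ± 0.13, Klf6 by 1.46 ± 0.21 and the ubiquitin ligase gene Fbxo32 by 0.90 ± 0.13. PI3K pathway components rose in 2 of 36 cases and fell in 1 (2 and 1 when adjusted over the list alone). Taken as 1 list they had camera adjusted p = 0.459, and adjusted p = 0.701 with an estimated correlation. Irs2 (0.70 ± 0.13, adjusted p = 0.0229) and Sgk1 (1.64 ± 0.26, adjusted p = 0.0155) rose, and Pik3r3 fell (-1.03 ± 0.16, adjusted p = 0.0142). Igf1r rose (0.85 ± 0.18, adjusted p = 0.0333) within an insulin and IGF axis of 17 genes in which 5 rose and 0 fell (5 and 1 when adjusted over the list alone). By camera the list had adjusted p = 0.153, and adjusted p = 0.509 with an estimated correlation. Many of these single-gene calls ended when 1 library was left out. Those of Igf1r, Irs2 and Fbxo32 ended whichever of the 4 libraries was left out, those of Pik3r3 and Klf6 without tamoxifen 1 or either alpelisib library, and those of Sgk1, Foxo1, Pdk4, Fdps and Msmo1 without either alpelisib library. The Idi1 call ended without tamoxifen plus alpelisib 2, and the Sqle call was kept.

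**Figure D2:**
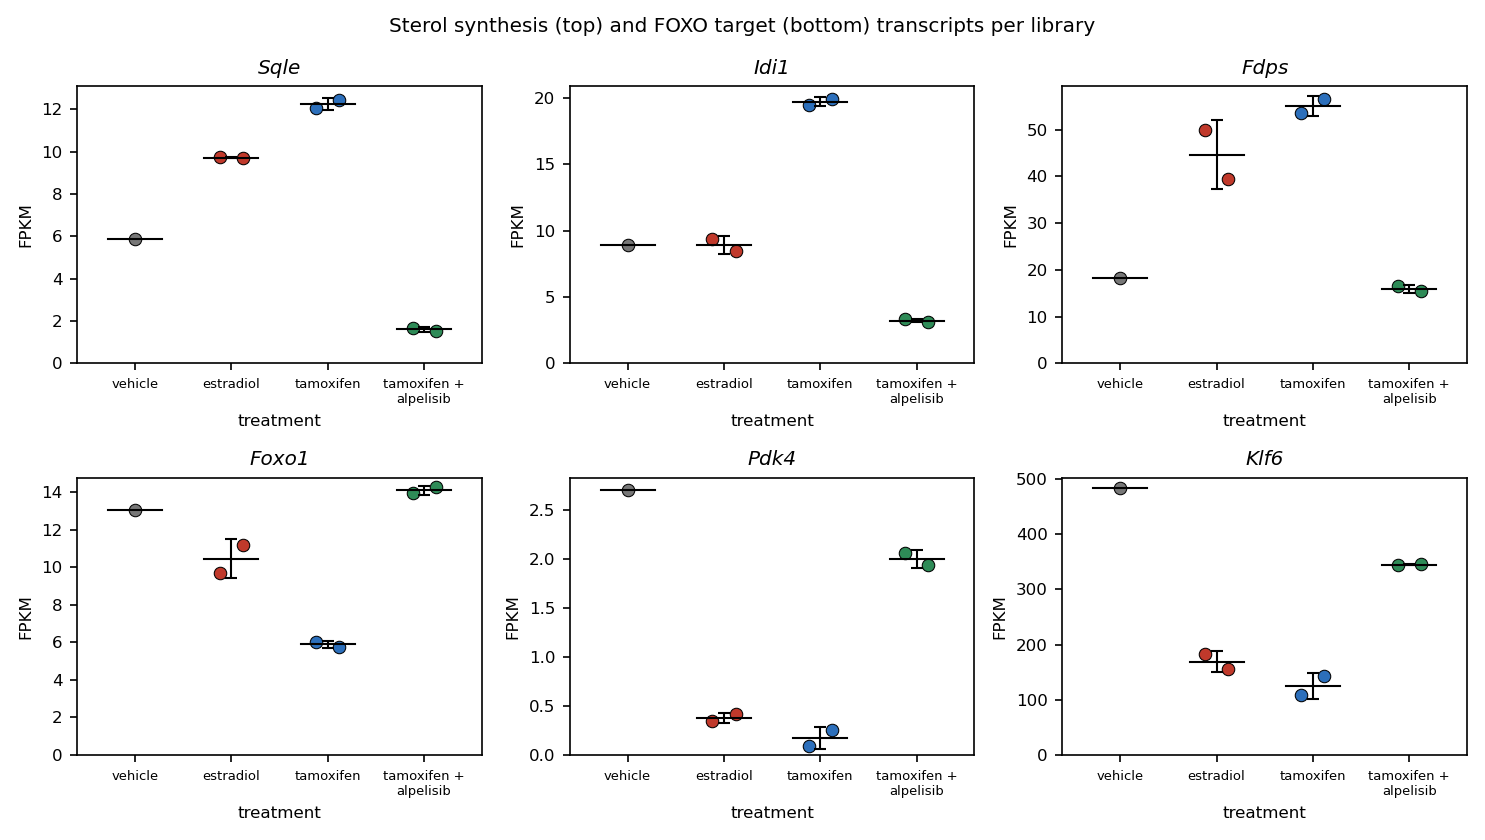
FPKM (vertical axes, from 0) of 3 sterol synthesis genes and 3 FOXO targets in each library, by treatment (horizontal axes); points are libraries, horizontal lines group means and bars ± SD (n = 2, none for the single vehicle library). Sqle lies at 1.53 and 1.7 with alpelisib against 12 and 12.5 with tamoxifen alone, and Foxo1 at 13.9 and 14.3 against 6.03 and 5.74.

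In the mitosis list 12 of 30 members fell and 0 rose (0 and 24 when adjusted over the list alone), with Ccna2 at -0.94 ± 0.13 and Tpx2 at -1.03 ± 0.14. The camera test gave adjusted p = 5.92e-10, and adjusted p = 0.281 with an estimated correlation. DNA replication genes fell in 5 of 30 cases and rose in 0 (0 and 9 when adjusted over the list alone), with Uhrf1 at -1.22 ± 0.13. Camera on this list gave adjusted p = 0.000192, and adjusted p = 0.281 with an estimated correlation. Mki67 had a log2 fold change of -1.07 ± 0.28 (adjusted p = 0.059) and passed with a pseudocount of 0.1 (adjusted p = 0.0299; 0.0242 to 0.294 over the alternatives). Squamous markers rose in 7 of 14 cases and fell in 0 (7 and 0 when adjusted over the list alone), with Krt14 at 2.59 ± 0.14 and Lgals7 at 2.54 ± 0.29. For the whole list, camera adjusted p = 5.95e-05, and adjusted p = 0.281 with an estimated correlation. The 10 largest increases included the cornified envelope genes Sprr2b (3.53 ± 0.42), Sprr2d and Sprr2e, whose near-identical copies can share reads, together with Psca, from 1.18 ± 1.1 to 36.1 ± 1.22 FPKM (SD, n = 2 each), and Slurp1. They also held the neutrophil-attracting chemokine genes Cxcl5, Cxcl2 and Ppbp, with S100a9 and Ctgf, at log2 fold changes down to 2.98. Innate defense genes rose in 8 of 22 cases and fell in 0 (9 and 1 when adjusted over the list alone), among them Cxcl5 (3.53 ± 0.18) and Defb1 (1.99 ± 0.16). Tested together with camera, these genes had adjusted p = 0.00591, and adjusted p = 0.657 with an estimated correlation. Immediate early genes rose in 5 of 23 cases and fell in 0 (5 and 0 when adjusted over the list alone), led by Ctgf (3.41 ± 0.31) and Fosl1 (2.55 ± 0.36). As a set they had camera adjusted p = 8.11e-05, and adjusted p = 0.701 with an estimated correlation. Tamoxifen metabolism and xenobiotic genes rose in 5 of 19 cases and fell in 0 (7 and 0 when adjusted over the list alone), with Sult1d1 at 2.65 ± 0.21. Their camera adjusted p was 0.000285, and adjusted p = 0.424 with an estimated correlation. Endoplasmic reticulum stress genes fell in 4 of 20 and rose in 0 (1 and 8 when adjusted over the list alone; camera adjusted p = 0.0261, and adjusted p = 0.738 with an estimated correlation), a call lost without tamoxifen replicate 2 (adjusted p = 0.135; 0.00484 to 0.135 over the alternatives). The decreases outside sterol synthesis included Il1r1, Crabp2, Lypd8, Ankrd37, Mgat4c and the spermidine synthase gene Srm (-1.88 ± 0.18), and the beta globin genes Hbb-bt and Hbb-b1, at -2.10 and -2.09.

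Marker lists of other cells also moved between these groups. Of 13 neutrophil and eosinophil markers 3 were measured, and 2 rose and 0 fell (2 and 0 when adjusted over the list alone). Taken as 1 list they had camera adjusted p = 0.0354, and adjusted p = 0.381 with an estimated correlation. This call was lost without tamoxifen replicate 2, with a pseudocount of 0.1 and with no filter on low values (adjusted p = 0.0744, 0.0751 and 0.331; 0.0194 to 0.331 over the alternatives). S100a8 (3.03 ± 0.16) and S100a9 (2.98 ± 0.53) rose and also belong to the innate defense list. The S100a9 call ended with a pseudocount of 0.1 (adjusted p = 0.161; 0.00803 to 0.161 over the alternatives) and whichever of the 4 libraries was left out, where that of S100a8 was kept, and Ly6g had a log2 fold change of -0.29 ± 0.50 (adjusted p = 0.755). Whether S100a8 and S100a9 come from granulocytes or from epithelium was not tested. Mesothelial markers rose in 5 of 6 cases and fell in 0 (5 and 0 when adjusted over the list alone), with Upk3b at 1.22 ± 0.14. By camera the list had adjusted p = 0.000607, and adjusted p = 0.281 with an estimated correlation. Smooth muscle markers fell in 5 of 9 cases and rose in 0 (1 and 6 when adjusted over the list alone; camera adjusted p = 0.00462, and adjusted p = 0.281 with an estimated correlation), with Acta2 at -1.41 ± 0.16, and erythroid markers fell in 3 of 5 cases and rose in 0 (0 and 3 when adjusted over the list alone; camera adjusted p = 0.00112, and adjusted p = 0.381 with an estimated correlation). Stromal markers rose in 4 of 17 cases and fell in 1 (5 and 2 when adjusted over the list alone), with a median of -0.11, a mean of 0.11 and an upward test. The camera test gave adjusted p = 0.895, and adjusted p = 0.896 with an estimated correlation. The uterine estrogen response list had 4 members higher and 4 lower of 30 (5 and 8 when adjusted over the list alone), with a median of -0.10 and a mean of 0.29. Camera on this list gave adjusted p = 0.51, and adjusted p = 0.865 with an estimated correlation. Log2 fold changes of the hormone receptors and of their usual target genes were 0.03 ± 0.25 for Esr1 (adjusted p = 0.958), -0.37 ± 0.12 for Pgr (adjusted p = 0.0997), -0.11 ± 0.19 for Greb1 (adjusted p = 0.744) and -0.57 ± 0.25 for Ltf (adjusted p = 0.192). For Ccnd1, Igf1, Irs1, Insr, Pik3ca and Txnip the adjusted p were 0.435, 0.702, 0.196, 0.303, 0.483 and 0.832.

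In all 1445 genes passed, 853 higher and 592 lower with alpelisib, and 555 changed at least 2-fold, 433 of these higher. Camera called 7 lists upward and 7 downward. The count depended on single libraries: it was 297 and 676 without tamoxifen 1 or 2, and 20 and 10 without tamoxifen plus alpelisib 1 or 2. Of the 41 genes named here that passed, 31, 36, 5 and 3 still passed in those runs, while the list calls for sterol synthesis and FOXO targets had adjusted p of at most 9.70e-12 and 3.98e-07 in each. Both of these list calls were lost with an estimated correlation (adjusted p = 0.281 for each), as were the other 12. Each run without 1 library leaves 2 residual degrees of freedom instead of 3. That alone cannot account for counts that differ widely among these runs, as it is the same in all of them. The replicate spread of the shortened group also leaves the pooled estimate. That spread was smaller with tamoxifen plus alpelisib than with tamoxifen (median chi-square against fragment sampling 1.08 and 3.73). How much this adds was not tested. A lower count therefore does not tell whether the library left out carried the changes.

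A further question is whether alpelisib turned back what tamoxifen had changed. Of the 4807 genes that differed between tamoxifen and vehicle, 72.4% lay in the opposite direction when alpelisib was added, 73.3% of those higher and 71.9% of those lower. Both comparisons use the tamoxifen libraries, which alone brings opposite directions: 20 simulated sets with no alpelisib effect gave a mean of 55.4% and at most 56.1%. These sets drew noise independently for each gene, with the same spread in all groups. In the data the tamoxifen replicates varied more than those with alpelisib (median chi-square against fragment sampling 3.73 and 1.08). Shifts of a whole library were not simulated either, so the shared libraries alone could give a larger share and a wider range. With tamoxifen 1 in the first comparison and tamoxifen 2 in the second the share was 71%, and 68.3% the other way round. Of the genes higher with tamoxifen, 76.6% were opposed in the first of these runs and 61% in the second. Of those lower, 68.1% and 73.7% were. The share by direction thus depended on which tamoxifen library was used. Genes that rose with tamoxifen and fell with alpelisib numbered 281, and 485 fell and then rose, while 90 rose in both and 52 fell in both. The shared tamoxifen libraries enter these counts too, and what they alone would give for them was not simulated.

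Estradiol against vehicle gives the reference response to an estrogen. Every one of the 30 measured mitosis genes rose (30 also when adjusted over the list alone), with Ccnb1 at 3.29 ± 0.18 and Ccna2 at 3.01 ± 0.15, and Mki67 went from 1.17 to 23.5 ± 9.76 FPKM (SD, n = 2; log2 3.44 ± 0.34, adjusted p = 0.00128). For the whole list, camera adjusted p = 5.74e-16, and adjusted p = 0.247 with an estimated correlation. DNA replication genes rose in 25 of 30 cases and fell in 0 (27 and 0 when adjusted over the list alone), with Uhrf1 at 2.28 ± 0.16. Tested together with camera, these genes had adjusted p = 6.85e-09, and adjusted p = 0.247 with an estimated correlation. Pgr rose from 15.2 to 38.3 ± 1.57 FPKM (SD, n = 2; log2 1.28 ± 0.15, adjusted p = 0.00204) and Ltf by 4.08 ± 0.30, while Klk1 fell from 57 to 0.486 ± 0.354 FPKM (log2 -5.31 ± 0.42, adjusted p = 0.000729). The other largest increases were in Spink12, Mmp7, Pigr, Uox, H2-Q7, Pglyrp1, Ccdc88b, Steap1 and Il1f6, from 3.95 to 5.73, and the other largest decreases in Gdf15, Plaur, Pla2g10, Efhd1, Timp3, Ctgf, Mt3, Ppbp and Fosl1, from -4.90 to -4.12. H2-Q7 has close relatives with which it can share reads. The stress-induced cytokine Gdf15 stood at 1237 FPKM in the vehicle library and 43 ± 20.5 with estradiol (SD, n = 2).

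Of the uterine estrogen response genes 17 of 30 rose and 7 fell (17 and 7 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0718, and adjusted p = 0.679 with an estimated correlation), whereas with median-of-ratios scaling, with quantile normalization and with no filter on low values it did (adjusted p = 0.0204, 0.0132 and 0.0255; 0.0132 to 0.121 over the alternatives). Interferon response genes rose in 27 of 29 cases and fell in 0 (28 and 1 when adjusted over the list alone), with Gbp3 at 3.16 ± 0.15. As a set they had camera adjusted p = 1.45e-11, and adjusted p = 0.495 with an estimated correlation. The limit of the single vehicle library given for this list with tamoxifen holds here too. Macrophage and dendritic cell markers rose beside them in 6 of 10 cases and fell in 0 (6 and 0 when adjusted over the list alone; camera adjusted p = 0.00793, and adjusted p = 0.679 with an estimated correlation), with Mpeg1 at 2.72 ± 0.15, a call lost without estradiol replicate 1 (adjusted p = 0.0514; 0.000668 to 0.0514 over the alternatives). Smooth muscle markers fell in 8 of 9 cases and rose in 0 (0 and 8 when adjusted over the list alone; camera adjusted p = 3.43e-06, and adjusted p = 0.247 with an estimated correlation), with Acta2 at -3.96 ± 0.20, and stromal markers fell in 9 of 17 and rose in 3 (3 and 9 when adjusted over the list alone; camera adjusted p = 0.00463, and adjusted p = 0.376 with an estimated correlation). The stromal call was lost with a filter of 1 FPKM in at least 2 libraries (adjusted p = 0.154; 0.00173 to 0.154 over the alternatives). The immediate early genes, which handling of tissue can also induce, fell in 10 of 23 cases and rose in 0 (0 and 11 when adjusted over the list alone), with Fosl1 at -4.12 ± 0.44. Their camera adjusted p was 7.88e-06, and adjusted p = 0.679 with an estimated correlation. Ribosomal protein genes fell in 16 of 74 cases and rose in 0 (0 and 0 when adjusted over the list alone; camera adjusted p = 3.32e-14, and adjusted p = 0.679 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.215; 5.96e-17 to 0.215 over the alternatives). Irs1 rose (1.33 ± 0.19, adjusted p = 0.00391), Irs2 fell (-1.44 ± 0.16, adjusted p = 0.00171) and Ccnd1 fell (-1.21 ± 0.19, adjusted p = 0.0055). Esr1 did not pass (0.44 ± 0.30, adjusted p = 0.292) but did without estradiol replicate 1 (adjusted p = 0.0179; 0.0179 to 0.75 over the alternatives). For Greb1, Igf1, Igf1r, Insr, Pik3ca, Foxo1 and Txnip the adjusted p were 0.381, 0.97, 0.206, 0.96, 0.229, 0.184 and 0.625.

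Between estradiol and vehicle 4366 genes passed, 2793 higher and 1573 lower with estradiol, and 2271 changed at least 2-fold. With median-of-ratios scaling 4385 genes passed, 2140 of them higher and 2245 lower. Without estradiol 2, the library whose depth is left open, 3880 genes passed. Camera called 7 lists upward and 6 downward. Tamoxifen and estradiol moved many genes the same way against vehicle: 1018 rose with both, 1166 fell with both and 236 went opposite ways. Across genes the log2 fold changes of these comparisons had Pearson's r of 0.585, but genes are not independent replicates and the single vehicle library enters both. In 20 simulated sets with no effect, r had a mean of 0.664, so r cannot separate a shared response from the shared library. The same sets had a mean of 0.1 genes called the same way in both, against 2184. With no effect in any group the adjustment leaves hardly any calls, so this count could not have come out otherwise and decides nothing. The covariance in these sets was 0.0471, against 0.556. That argues against vehicle noise of the assumed spread, drawn independently for each gene, as the whole source of the covariance. How many of the 2184 rest on that library with effects present was not simulated. A departure of the vehicle library itself would enter both comparisons alike.

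**Figure D3:**
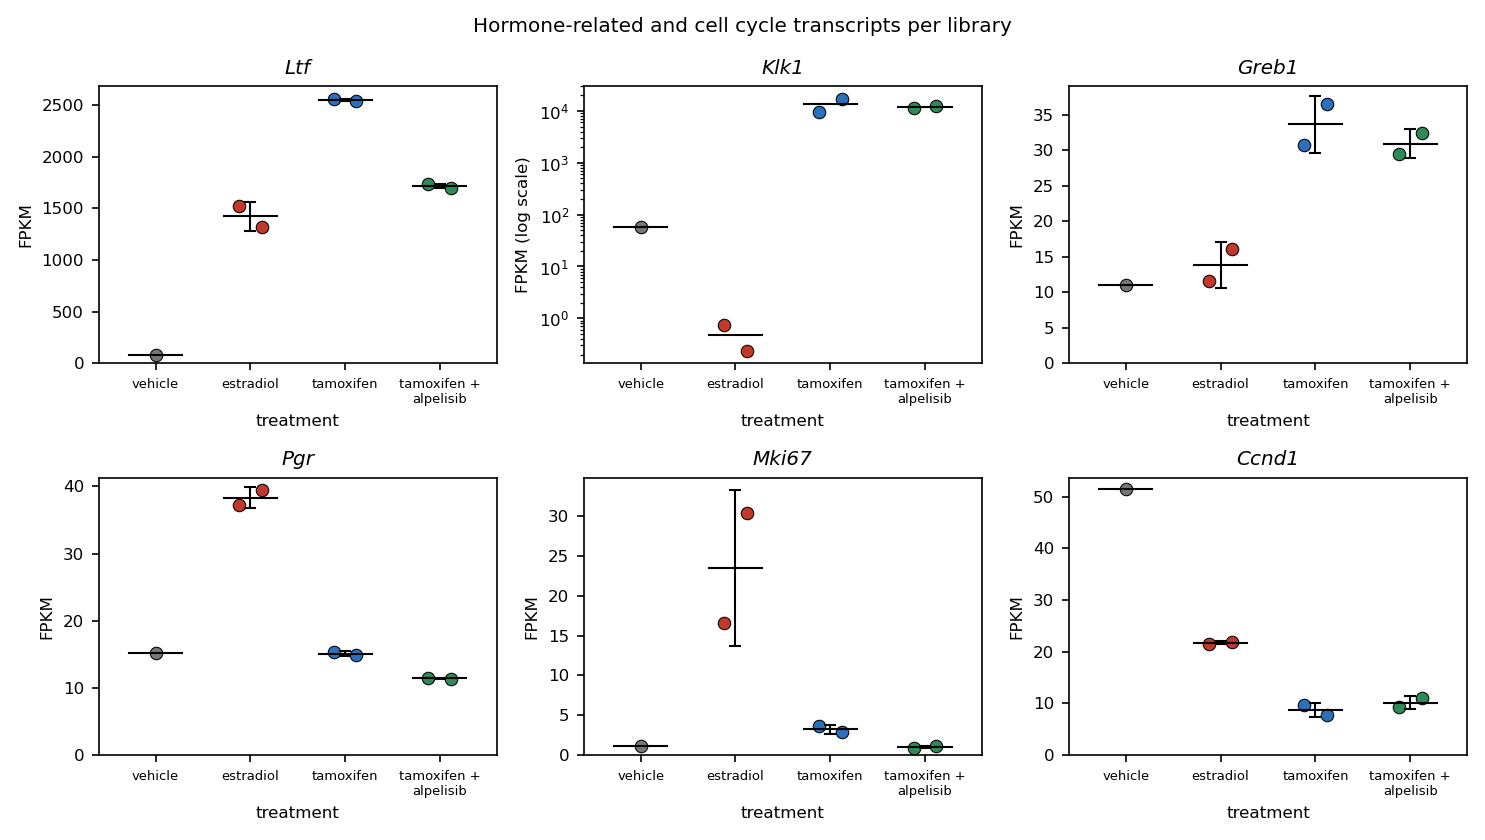
FPKM (vertical axes, from 0 except the log axis for Klk1) of 6 hormone-related and cell cycle genes in each library, by treatment (horizontal axes); points are libraries, horizontal lines group means and bars, on the linear axes, ± SD (n = 2, none for the single vehicle library). Ltf lies at 83.1 in vehicle and between 1324 and 2556 in the other 6 libraries, while Mki67 lies at 16.6 and 30.4 with estradiol and at most 3.65 elsewhere.

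Tamoxifen against estradiol addresses where the drug departs from the hormone. All 30 measured mitosis genes and all 30 DNA replication genes were lower with tamoxifen (30 of 30 in each list also when adjusted over the list alone), with camera adjusted p = 2.32e-09, and adjusted p = 0.263 with an estimated correlation for mitosis, and camera adjusted p = 3.04e-09, and adjusted p = 0.263 with an estimated correlation for replication. Bub1b had a log2 fold change of -2.52 ± 0.14, Mcm3 one of -2.53 ± 0.13 and Mki67 one of -2.48 ± 0.28 (adjusted p = 0.00105). Estrogen response genes were nevertheless higher with tamoxifen in 18 of 30 cases and lower in 5 (18 and 5 when adjusted over the list alone). Taken as 1 list they had camera adjusted p = 6.28e-08, and adjusted p = 0.263 with an estimated correlation. In the main fit of estradiol against vehicle, however, this list was not called and Klk1 fell. The higher values with tamoxifen are therefore not a measure of stronger estrogen action. Klk1 went from 0.486 ± 0.354 FPKM with estradiol to 13337 ± 5627 with tamoxifen (SD, n = 2 each; log2 13.09 ± 0.35, adjusted p = 1.65e-05), and Clca1 and the water channel Aqp5 were higher by 4.35 ± 0.23 and 3.82 ± 0.22. Klk1b24 and Prss29 were listed at 0 in both estradiol libraries and at 475 and 611, and 198 and 277 FPKM with tamoxifen, and Klk1b27, Klk1b21, Penk, Fabp5, Hba-a2, Arg1 and Otop1 were higher by 5.50 to 11.25, with the same limit on kallikrein and globin copies. The Hba-a2 call was lost without either tamoxifen library (adjusted p = 0.0562 and 0.0514 without replicates 1 and 2; 0.0012 to 0.0562 over the alternatives). Stra6, the cellular receptor for vitamin A bound to its carrier, fell from 63.5 ± 3.86 to 0.343 ± 0.0348 FPKM (SD, n = 2 each; log2 -5.58 ± 0.12), and Ldhb, Alox15, Slc25a48, Ap3b2, Ifitm1, Vwa2, Irg1, Tnfaip2 and Il17rb fell, with log2 fold changes from -5.27 to -4.18.

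Collagen and matrix genes were lower with tamoxifen than with estradiol in 25 of 31 cases and higher in 1 (2 and 25 when adjusted over the list alone), with Col14a1 at -3.27 ± 0.14 against Postn at 3.79 ± 0.13. By camera the list had adjusted p = 0.000108, and adjusted p = 0.263 with an estimated correlation. Stromal markers were lower in 9 of 17 cases and higher in 2 (2 and 9 when adjusted over the list alone; camera adjusted p = 0.541, and adjusted p = 0.629 with an estimated correlation; 0.0405 to 0.739 over the alternatives), whereas smooth muscle markers were higher in 7 of 9 and lower in 0 (7 and 0 when adjusted over the list alone; camera adjusted p = 0.000504, and adjusted p = 0.263 with an estimated correlation). Wnt signaling genes were lower in 18 of 24 cases and higher in 1 (1 and 18 when adjusted over the list alone), with Wnt7a at -3.05 ± 0.17. The camera test gave adjusted p = 0.00263, and adjusted p = 0.263 with an estimated correlation. Genes of MHC class II presentation were lower in 6 of 7 cases and higher in 0 (0 and 6 when adjusted over the list alone; camera adjusted p = 0.0328, and adjusted p = 0.603 with an estimated correlation), with H2-Ab1 at -3.20 ± 0.16, and macrophage and dendritic cell markers were lower with them in 9 of 10 and higher in 0 (1 and 9 when adjusted over the list alone; camera adjusted p = 0.00998, and adjusted p = 0.603 with an estimated correlation), with Mpeg1 at -2.66 ± 0.12. Without estradiol replicate 1 the MHC class II list was no longer called (adjusted p = 0.0958; 0.00381 to 0.0958 over the alternatives). Whether the estradiol libraries held more stromal or immune cells was not tested. Such a difference could give the lower matrix, macrophage and MHC class II values too. Endoplasmic reticulum stress genes were higher in 13 of 20 cases and lower in 0 (13 and 0 when adjusted over the list alone), with Herpud1 at 1.41 ± 0.21. Camera on this list gave adjusted p = 1.40e-06, and adjusted p = 0.485 with an estimated correlation. Sterol synthesis genes were higher in 10 of 23 cases and lower in 3 (10 and 3 when adjusted over the list alone), with Insig1 at 1.30 ± 0.14. For the whole list, camera adjusted p = 0.00128, and adjusted p = 0.58 with an estimated correlation. Fatty acid synthesis genes were lower in 12 of 15 cases and higher in 2 (2 and 12 when adjusted over the list alone; camera adjusted p = 0.0495, and adjusted p = 0.485 with an estimated correlation), a call lost with a pseudocount of 0.1, with a filter of 1 FPKM in at least 2 libraries, without estradiol replicate 2 and without tamoxifen replicate 2 (adjusted p = 0.0703, 0.0522, 0.0911 and 0.0823; 0.0162 to 0.0911 over the alternatives). PI3K pathway components were lower in 13 of 36 cases and higher in 2 (2 and 13 when adjusted over the list alone), among them Irs1 (-1.56 ± 0.15, adjusted p = 0.000655). Tested together with camera, these genes had adjusted p = 0.422, and adjusted p = 0.603 with an estimated correlation.

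Against estradiol, tamoxifen also left Pgr lower (-1.29 ± 0.12, adjusted p = 0.000577) and Greb1 higher (1.23 ± 0.19, adjusted p = 0.00316). Igf1r (-1.33 ± 0.18), Foxo1 (-0.73 ± 0.13) and Ccnd1 (-1.24 ± 0.15) were lower and Txnip (1.60 ± 0.18) was higher. The calls of 3 genes near the threshold were lost without tamoxifen replicate 1, without tamoxifen replicate 2 and in other alternatives. They were Esr1 (-0.91 ± 0.25, adjusted p = 0.0242; without those replicates 0.0695 and 0.10, and 0.00376 to 0.107 over the alternatives), Ltf (0.84 ± 0.25, adjusted p = 0.0316; without those replicates 0.0993 and 0.10, and 0.00425 to 0.687 over the alternatives) and Irs2 (-0.42 ± 0.13, adjusted p = 0.0353; without those replicates 0.0839 and 0.14, and 0.0155 to 0.447 over the alternatives). With median-of-ratios scaling the calls of Esr1 and Irs2 were lost too, and with quantile normalization and without estradiol replicate 2 those of Ltf and Irs2. Pik3ca did not pass (adjusted p = 0.0539) but did without estradiol replicate 1 (adjusted p = 0.0265; 0.0265 to 0.799 over the alternatives), and Igf1 and Insr had adjusted p of 0.901 and 0.604. In all 5977 genes passed, 1519 higher and 4458 lower with tamoxifen, and 2453 changed at least 2-fold. With median-of-ratios scaling 5618 genes passed, 2762 of them higher and 2856 lower, so the uneven split depends on the scaling. That scaling brings the typical gene close to no change, which by itself makes the split near even. It therefore does not tell whether the uneven split is real. Without estradiol 2 the count was 5153. Camera called 12 lists upward and 9 downward; the ribosomal protein list was called upward (adjusted p = 0.00305, and adjusted p = 0.761 with an estimated correlation) with 0 of 74 members past the threshold, and downward with quantile normalization, as its median moved from 0.15 to -0.32. Without estradiol replicate 2 that list was not called (adjusted p = 0.622; 7.57e-07 to 0.622 over the alternatives).

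Tamoxifen plus alpelisib against vehicle addresses what remained of the tamoxifen response under the inhibitor. Klk1 (7.68 ± 0.42), Klk1b27 (7.50 ± 0.21), Arg1 (7.42 ± 0.30), Prss29, Aoc1 and Spink12 stayed among the 10 largest increases, joined by Sprr2d (7.06 ± 0.60), the interleukin gene Il1a, from 3.17 to 414 ± 21.4 FPKM (SD, n = 2; log2 6.63 ± 0.21), and by Mmp7 and Pglyrp1. Decreases were led by Il17rb, Tgfbi, Ccl21a, Pla2g10, Timp3, Mt3, Npl, Efhd1, Wnt11 and Fndc5, with log2 fold changes from -5.93 to -3.88. Estrogen response genes rose in 21 of 30 cases and fell in 3 (22 and 4 when adjusted over the list alone). As a set they had camera adjusted p = 1.95e-09, and adjusted p = 0.251 with an estimated correlation. Innate defense genes rose in 15 of 22 cases and fell in 3 (16 and 3 when adjusted over the list alone), with Pigr at 5.11 ± 0.21 and Cxcl5 at 3.69 ± 0.21. Their camera adjusted p was 1.22e-08, and adjusted p = 0.299 with an estimated correlation. Of the 3 measured granulocyte markers 2 rose, S100a8 (3.03 ± 0.20) and S100a9 (4.95 ± 0.65), and 0 fell (2 and 0 when adjusted over the list alone; camera adjusted p = 0.0122, and adjusted p = 0.275 with an estimated correlation), a call lost with no filter on low values (adjusted p = 0.0879; 0.00889 to 0.0879 over the alternatives). Mitosis genes rose in 1 of 30 cases and fell in 0 (0 and 0 when adjusted over the list alone; camera adjusted p = 0.238, and adjusted p = 0.775 with an estimated correlation), while DNA replication genes fell in 16 of 30 and rose in 1 (1 and 17 when adjusted over the list alone; camera adjusted p = 0.00148, and adjusted p = 0.251 with an estimated correlation), with Mcm3 at -2.16 ± 0.16. Sterol synthesis genes fell in 11 of 23 cases and rose in 0 (0 and 12 when adjusted over the list alone), with Sqle at -1.40 ± 0.15. Taken as 1 list they had camera adjusted p = 0.0225, and adjusted p = 0.77 with an estimated correlation. Stromal markers were lower beside them in 13 of 17 cases and higher in 1 (1 and 15 when adjusted over the list alone). By camera the list had adjusted p = 0.000103, and adjusted p = 0.251 with an estimated correlation. Foxo1 had a log2 fold change of 0.11 ± 0.16 (adjusted p = 0.64) and Mki67 one of -0.11 ± 0.34 (adjusted p = 0.833). In all 4299 genes passed, 1619 higher and 2680 lower, and 2335 changed at least 2-fold. With median-of-ratios scaling 4366 genes passed, 2158 of them higher and 2208 lower, and without tamoxifen plus alpelisib 1 or 2 the counts were 1898 and 1941.

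Tamoxifen plus alpelisib against estradiol showed lower expression of all 30 mitosis genes and all 30 DNA replication genes (30 of 30 in each list also when adjusted over the list alone), with camera adjusted p = 5.51e-11, and adjusted p = 0.273 with an estimated correlation for mitosis, and camera adjusted p = 5.03e-10, and adjusted p = 0.26 with an estimated correlation for replication. Mki67 fell from 23.5 ± 9.76 to 1.02 ± 0.154 FPKM (SD, n = 2 each; log2 -3.54 ± 0.28, adjusted p = 0.00029). Squamous markers were higher in 9 of 14 cases and lower in 0 (10 and 0 when adjusted over the list alone), with Krt13 at 2.64 ± 0.14. The camera test gave adjusted p = 2.15e-07, and adjusted p = 0.273 with an estimated correlation. Lists of endothelial markers, of adipocyte markers and of collagens and matrix were called too, in each alternative at the preset correlation. Immediate early genes were higher in 17 of 23 cases and lower in 1 (17 and 1 when adjusted over the list alone), with Fosl1 at 3.78 ± 0.36. Camera on this list gave adjusted p = 2.15e-07, and adjusted p = 0.584 with an estimated correlation. FOXO targets were higher in 14 of 30 cases and lower in 6 (14 and 6 when adjusted over the list alone), with Cited2 at 3.09 ± 0.31. For the whole list, camera adjusted p = 0.00277, and adjusted p = 0.484 with an estimated correlation. Fatty acid synthesis genes were lower in 12 of 15 cases and higher in 2 (2 and 12 when adjusted over the list alone), with Thrsp at -4.04 ± 0.19 and Scd2 at -2.32 ± 0.14. Tested together with camera, these genes had adjusted p = 0.0198, and adjusted p = 0.346 with an estimated correlation. Klk1 (12.99) and Klk1b27 (10.34) again led the increases and Stra6 (-5.48) and Ldhb (-4.79) the decreases. Kap was listed at 0 in both estradiol libraries and in vehicle, and at 64.1 and 70.5 FPKM with tamoxifen plus alpelisib. In all 6548 genes passed, 1935 higher and 4613 lower, and 2954 changed at least 2-fold. With median-of-ratios scaling 6370 genes passed, 3209 of them higher and 3161 lower, and without tamoxifen plus alpelisib 1 or 2 the counts were 3875 and 3915.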

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

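Of the results for named genes under the alternatives, 2180 stayed on the same side of the threshold, 123 lost their call, 5 gained one and 0 reversed. For gene lists these were 2101, 151, 26 and 2. A change of direction counted as a reversal only with a call in at least 1 of the runs compared. Results called in neither run may therefore have changed direction among those that stayed. The lists that reversed were the ribosomal proteins in tamoxifen against estradiol and in tamoxifen plus alpelisib against estradiol, both under quantile normalization (adjusted p = 0.00161 and 0.000121), where the cause was not tested. Requiring a 2-fold change left 2746 genes for tamoxifen and 2271 for estradiol against vehicle, 555 for alpelisib added to tamoxifen, 2453 for tamoxifen against estradiol, and 2335 and 2954 for tamoxifen plus alpelisib against vehicle and estradiol. Leaving out each replicate gave 10 to 676 genes for alpelisib added to tamoxifen, 3680 to 3847 for tamoxifen and 3880 to 5035 for estradiol against vehicle, 4306 to 6071 for tamoxifen against estradiol, and 1898 to 1941 and 3875 to 6607 for tamoxifen plus alpelisib against vehicle and estradiol; such runs have fewer samples, and a lone library is assumed to vary like the other groups. For alpelisib added to tamoxifen no filter left 870 genes, with 18198 tested instead of 12314. The replicate block left 586 there, 5086 for tamoxifen and 5808 for tamoxifen plus alpelisib against estradiol; since mouse numbers do not pair the groups (correlations of deviations -0.403, -0.182 and 0.273), calls lost under it say nothing of the size of an effect. With an estimated correlation, which rests on 3 residual degrees of freedom, 0 of 99 list calls held. Median-of-ratios scaling gave 100. The share of tamoxifen changes opposed under alpelisib moved from 72.4% to 71% and 68.3% with the tamoxifen libraries split, and the 2184 genes shared with estradiol to 2419 with median-of-ratios scaling. Choices set in advance that need counts (another count test, another scaling of counts and a minimum of 10 counts) were not run, as the values are FPKM. An FPKM of 1 on a transcript of 1 kb rests on about 16 to 19.5 fragments in the 6 libraries with an estimated depth. Per library 5 to 11 of 268 housekeeping family genes were listed at 0, and the cause was not tested.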

Other observations

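The counts by gene family and 3 of the tests that follow, the correction for the share of abundant genes and those on stromal and endothelial cells and on reads shared between globin copies, were chosen only after the result was seen. Families of genes with a common symbol stem were counted by how many members changed at least 2-fold past the threshold, with a one-sided Fisher test adjusted over 312 families. With tamoxifen against vehicle, transmembrane serine proteases (Tmprss, 7 of 9; adjusted p = 0.000337), kallikreins (Klk, 7 of 12; adjusted p = 0.00294), the interleukin 1 family (Il1, 6 of 10; adjusted p = 0.00658), keratins (Krt, 8 of 23; adjusted p = 0.0354) and oligoadenylate synthetases (Oas, 4 of 6; adjusted p = 0.0448) passed an adjusted p of 0.05, all for increases. With alpelisib added, small proline-rich proteins (Sprr, 7 of 12; adjusted p = 1.34e-05), keratins (Krt, 8 of 23; adjusted p = 0.000105), chemokines (Cxcl, 5 of 11; adjusted p = 0.00184), dual specificity phosphatases (Dusp, 6 of 18; adjusted p = 0.00184), Krüppel-like factors (Klf, 5 of 13; adjusted p = 0.00334), claudins (Cldn, 4 of 12; adjusted p = 0.031) and insulin-like growth factor binding proteins (Igfbp, 3 of 6; adjusted p = 0.0356) did. Members of some of these families can share reads and lie side by side in the genome, so these p values are too small there. The values of Apoa2, a liver apolipoprotein gene, were 46.2 and 0 FPKM with estradiol, 8.24 with vehicle, 11.9 and 47 with tamoxifen, and 0.221 and 23.9 with tamoxifen plus alpelisib.

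With the values as deposited, most genes that differed between tamoxifen and estradiol were lower with tamoxifen (1519 higher and 4458 lower), but the split was near even with median-of-ratios scaling (2762 and 2856) and with quantile normalization (2523 and 2756). Both of these bring the typical gene close to no change, so a near-even split follows from them and does not tell whether the uneven one is real. Abundant genes that take a larger part of the tamoxifen libraries could lower all others, but without the 22 most abundant genes 27.6% of called genes were higher, against 22.2% with them, each fit rescaled to its own total. With deposited values corrected for the share of these genes alone it was 31.9%, against 25.4%, and the median log2 fold change moved from -0.26 to -0.17. Both shares stay below the bound fixed in advance, which argues against this as the whole explanation, though not as a part. Gene length may play a part: the median log2 fold change was -0.10 in the shortest of 5 equal classes of genes and -0.46 in the longest (Spearman's rho -0.17 over the 96.9% of genes with a length), which leaves that explanation open.

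With alpelisib 17 of 23 sterol synthesis genes were lower, and the list call was lost with an estimated correlation (adjusted p = 0.281). If a single library decided this, some pair of libraries would lack it, but the highest of the 4 pairwise list medians was -0.93. A loss of stromal and endothelial cells could lower transcripts too, but the lower of those list medians was -0.14 against -0.97 for sterol synthesis; 0 of the 25 sterol genes sit in another list. Both values argue against the explanation they tested. Other marker lists did move in this comparison: smooth muscle and erythroid markers fell and mesothelial markers rose. Whether a change in those cells lowered the sterol synthesis genes was not tested.

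Hemoglobin transcripts were highest with tamoxifen, summing to 1529 and 1114 FPKM against 292 and 311 with alpelisib added, 88.6 and 129 with estradiol and 36.1 with vehicle. Blood carried into the cell preparation is a candidate source: the sum of the erythroid genes Alas2 and Slc4a1 in the lowest tamoxifen library was 3.08 times that in the highest other library, consistent with it, although Slc4a1 was listed at 0 in most libraries. Reads shared between globin copies would leave the summed globin alike, but the lowest of the 4 pairwise log2 ratios between tamoxifen and tamoxifen plus alpelisib was 1.84, which argues against that. How the cells were freed of blood is not given in the sources used here.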
